A study of Mus musculus with 14 samples.

How the data were processed

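RNA sequencing of mouse pancreatic β-cells and whole islets was analysed from the raw gene counts deposited by the authors, whole numbers of reads per gene with no normalization, in 3 tables that share 37310 Ensembl gene identifiers. The first table holds 6 libraries of wild-type β-cells, 3 from neonates at postnatal day 6 and 3 from adults at day 45. The second holds 4 libraries of whole islets from mice 8 weeks old, 2 labelled TSC1 KO and 2 labelled control, with the prefix RC, whose meaning is not given in the sources used here. The third holds 4 libraries of whole islets from mice 4 weeks old, 2 labelled Db and 2 labelled control, with the prefix BKS, although the strain of all 14 libraries is given as C57BL/6. Each group was taken from the sample titles. Among the neonatal columns 2 carry the same heading, number 3, and none carries number 2. These are called neonatal replicates 3a and 3b, and all 3 neonatal columns were used as one group.

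Per the labels' protocols, islets were isolated, RNA was extracted with Trizol and libraries were made from small amounts of total RNA with the SMARTer Stranded kit, which marks the strand. How the β-cells were obtained is not given in the sources used here. Per the submitters' processing notes, cutadapt 1.13, GSNAP, HTSeq 0.7.1 and DESeq2 1.16.0 were used and the builds NCBIM37 and mm9 are named, with no role stated for either build and no strand setting for the counting. Genes that overlap an antisense partner and genes with close or near-identical copies are therefore uncertain: Ins1 and Ins2, the haemoglobin genes, the trypsinogens Prss1, Prss3 and Try5, Hspa1a and Hspa1b, H2-Q6, the ribosomal protein genes and Igf2os. The reference available here is a later build, so no coordinates are printed. It was used for gene symbols, which matched 32620 of the 37310 identifiers (87.4%), and for the GC content and length of the longest transcript of each gene.

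Rows that name no gene were kept out of library sizes and tests. In the β-cell table the gene rows held between 24.52% and 43.11% of all reads and the row for reads outside annotated features held between 16.33% and 32.53%. In adult replicate 3 unaligned reads made up 53.64%. In the table of Db and control islets gene rows held between 35.1% and 44.27%, and reads outside features between 42.5% and 49.56%. The table of TSC1 KO and control islets has no such rows, so these shares are unknown for it. Total gene counts per library ranged from 3507929 to 17688772. Shares of a library's counts have 95% Wilson intervals no wider than ± 0.0522 percentage points. Intervals and floors cover counting error only, because reads without molecular identifiers are not independent molecules. Replicates were compared by a chi-square of their counts over genes, which gave between 10.93 and 83.88 per degree of freedom within groups, so no pair looked like a library deposited again.

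Each comparison was fitted on its own table with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, two-sided, after filterByExpr (minimum count 10, minimum total count 15), TMM scaling and robust dispersion estimates, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. A gene past it is called higher or lower. Values are given as CPM, gene counts scaled to a common effective library total, mean ± SD, and log2 fold changes with their standard errors. Adjusted p-values without another name are from edgeR's quasi-likelihood test with that adjustment. Whether the libraries of a group come from separate animals is not stated, so p-values measure the spread between these samples, which may be technical. With 2 libraries per group the islet fits have 2 residual degrees of freedom before moderation across genes. A joint edgeR fit over the 8 islet libraries with a term per table and an interaction tested whether the TSC1 KO and Db effects differ.

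Before the data were examined, 29 gene lists were fixed. They are β-cell identity and maturity, immature and progenitor endocrine genes, β-cell disallowed genes, cell cycle, glycolysis, TCA cycle and pyruvate entry, nuclear OXPHOS subunits, mitochondrially encoded genes, mitochondrial biogenesis regulators, AMPK subunits and upstream kinases, mTORC1 components and regulators, cytosolic ribosomal proteins, ATF4 and amino acid response, ER chaperones and unfolded protein response, cholesterol and fatty acid synthesis, fatty acid oxidation, secretory granule and exocytosis, autophagy and lysosome, antioxidant and redox, circadian clock, immediate early and dissociation stress, and markers of other islet endocrine, acinar, duct, endothelial, mesenchymal, immune, erythroid, and neural and Schwann cells. Each was tested with camera (limma 3.58.1) against all other genes with a preset inter-gene correlation of 0.01, two-sided, adjusted over the lists of a comparison. Camera with an estimated correlation was an alternative, as was fry, which asks whether a list changed at all and not whether it differs from other genes. The estimated correlation is reported with each called list, and fry for the age signature and, for the lists, in the section on processing. With an estimated correlation camera also uses only the residual degrees of freedom, 2 in each islet fit. A call lost with it therefore need not reflect correlation between genes. Ranges over the other alternatives keep the preset correlation. The number of members called is given over all genes tested and adjusted over the list alone. The age signature is the 200 genes with the smallest p among those called higher at each age and tested in both tables, tested with camera in each islet comparison as 4 tests.

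The genes named in each comparison follow a rule fixed at the same time: the 10 largest changes each way among called genes whose groups do not overlap and whose mean log2 CPM is at least 2, skipping unnamed gene models; 19 genes fixed in advance; up to 4 members of each list; and up to 10 genes called in both islet comparisons. Any other name is said to have been chosen after its values were seen. Where a group had no count for a gene, the fold is a lower bound against a floor of 3 counts over the group's libraries, and where it had 1 to 3 counts the ratio is given with its counting interval.

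The fit was tested on simulated counts with 2-fold, 4-fold and 8-fold changes. For the β-cell comparison (13723 genes) it called 18.2%, 71.4% and 84.1% of the changed genes in the right direction, for the TSC1 KO comparison (14169 genes) 24.2%, 88.1% and 97%, and for the Db comparison (14129 genes) 49.3%, 93.9% and 100%. False calls were 4 of 114, 11 of 150 and 4 of 165. The simulation changed few genes, about equally in each direction, with genes independent and no GC trend or shift in composition. These rates belong to that setting and may not hold in these data. Alternatives fixed before the counts were opened were DESeq2 1.42.0, limma-voom, DESeq2's size factors, library size without TMM, TMM without marker and insulin genes, no filter on low counts, a filter at 1 CPM, the replicate number as a block in the islet comparisons, and each library left out in turn. Chosen after seeing the data were offsets removing the GC trend or the GC and length trends per library (lowess, span 0.3), the same with the block, thinning to the smallest library, and leaving out Ins1 and Ins2, mitochondrially encoded genes or marker genes. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.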

Results

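RNA was sequenced from mouse pancreatic β-cells, the insulin-secreting cells of the islets of Langerhans, and from whole islets, which also hold other endocrine, endothelial, mesenchymal and immune cells. The libraries form 6 groups. Wild-type β-cells were taken at postnatal day 6 (neonatal, n = 3) and day 45 (adult, n = 3). Islets labelled as a β-cell knockout of Tsc1 and their controls were taken at 8 weeks (n = 2 each). Islets labelled Db and their controls were taken at 4 weeks (n = 2 each). Neonatal libraries held 14589519, 14166621 and 15374425 gene counts and adult libraries 16222921, 15205318 and 12696006. TSC1 KO libraries were the smallest, at 4392206 and 3507929 against 5843371 and 6212629 in their controls, and Db libraries held 16897616 and 17688772 against 9020767 and 10117880 in theirs. The insulin genes Ins1 and Ins2 together took 2.62%, 2.36% and 1.83% of gene counts in neonatal and 6.93%, 7.22% and 4.36% in adult β-cells. They took 24.53% and 27.86% in RC control islets and 1.05% and 0.97% in TSC1 KO islets, and 61.04% and 70.03% in BKS control islets and 48.33% and 45.53% in Db islets. Mitochondrially encoded genes took 39.77% and 46.83% in TSC1 KO islets, against 12.36% and 9.05% in their controls and between 0.15% and 8.27% in all other libraries.

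**Figure D1:**
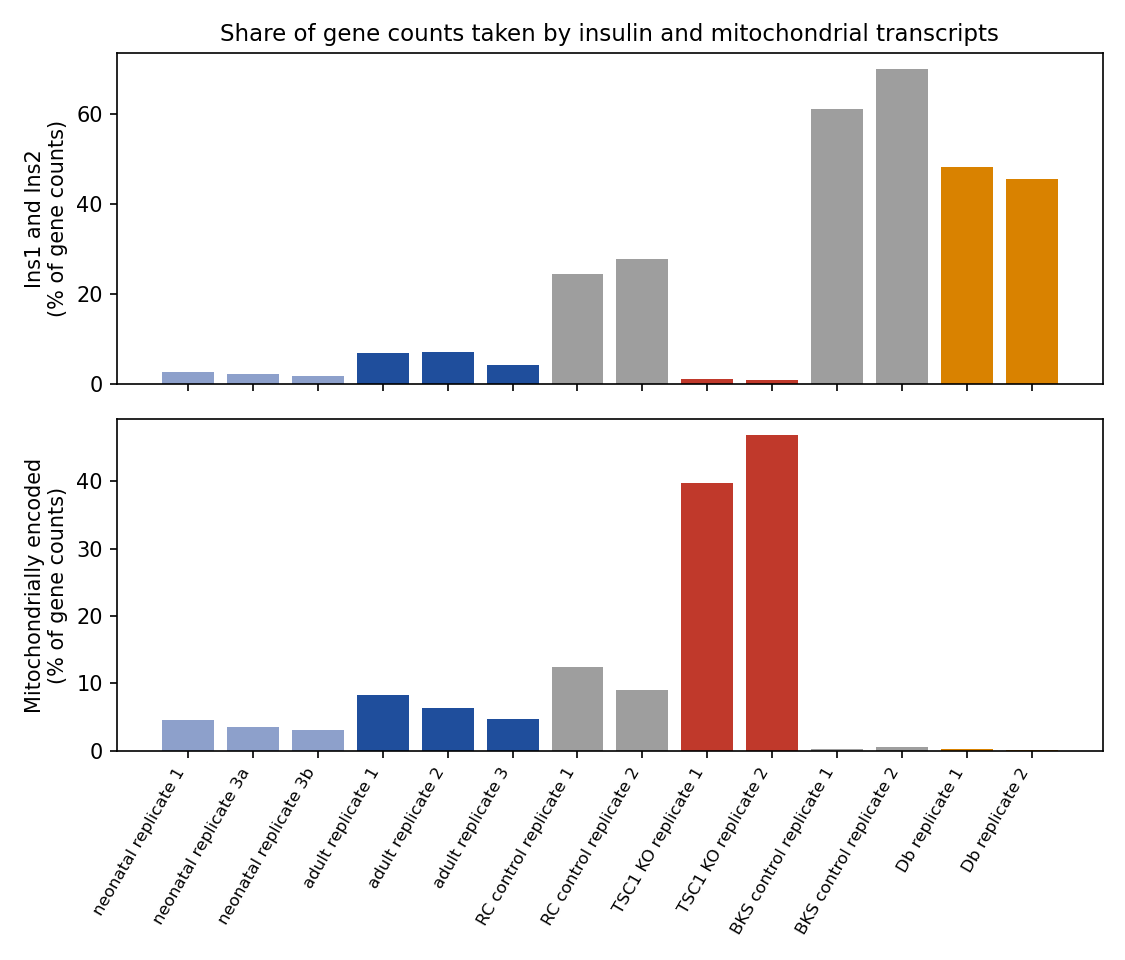
Bars give, for each of the 14 libraries, the percentage of gene counts taken by Ins1 and Ins2 (upper panel) and by mitochondrially encoded genes (lower panel), coloured by group. Insulin transcripts took 70.03% of counts in BKS control replicate 2 and 0.97% in TSC1 KO replicate 2, and mitochondrially encoded genes took 46.83% in the latter.

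The first comparison, of adult with neonatal β-cells (n = 3 each), addresses how β-cell transcripts differ across postnatal maturation. Transcripts of Ins2 (ENSMUSG00000000215) were 3.04-fold higher in adult cells, at 46110 ± 11830 CPM against 15160 ± 3254 (SD; log2 fold change 1.60 ± 0.20 SE, edgeR adjusted p = 0.000976), and those of Ins1 3.13-fold higher (log2 fold change 1.64 ± 0.26 SE, edgeR adjusted p = 0.00731; alternatives 8.72e-12 to 0.0657, the last without neonatal replicate 3a). These genes are close copies, so some of their reads may be assigned to the wrong one. Ucn3, which encodes urocortin 3, a peptide of mature β-cells, was 2.54-fold higher (log2 fold change 1.34 ± 0.24 SE, edgeR adjusted p = 0.00329), and G6pc2, the islet glucose-6-phosphatase subunit, 2.799-fold higher (log2 fold change 1.48 ± 0.20 SE, edgeR adjusted p = 0.000557). Tph1, the first enzyme of serotonin synthesis, rose from 23.7 ± 5.52 to 627 ± 176 CPM (SD; log2 fold change 4.72 ± 0.25 SE, edgeR adjusted p = 5.76e-08). In the other direction, Igf2bp3, a fetal RNA-binding protein, was 46.8-fold lower in adults (log2 fold change -5.55 ± 0.52 SE, edgeR adjusted p = 1.02e-05) and the imprinted gene Dlk1 17.6-fold lower (log2 fold change -4.14 ± 0.42 SE, edgeR adjusted p = 1.96e-05). For each gene named as higher or lower in any of the 3 comparisons, all libraries of a group lay on the same side of all libraries of the other.

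Of 14304 genes tested, 484 were called higher and 515 lower in adult cells, 307 and 347 of them by at least 2-fold. With library size as the only scaling the split was 321 higher and 872 lower, as the median of all genes then moved to -0.19. The count depended on which library was left out: 405, 430 or 463 genes were called without one adult library, and 904, 1380 or 767 without neonatal replicate 1, 3a or 3b. Of 81 called genes named by the fixed rule, 47 lost their call without at least 1 library. Among the 10 largest rises were the membrane-binding protein Cpne4 (6.32 ± 0.54), the anion exchanger Slc26a3 (5.82 ± 0.48), the opioid precursor Pdyn (5.36 ± 0.48) and Tmem47 (4.73 ± 0.78; log2 fold changes ± SE, edgeR adjusted p between 3.58e-06 and 0.00162). Among the largest falls were the potassium channel Kcnk9 (-5.05 ± 0.36, edgeR adjusted p = 8.53e-07) and the RNA-binding protein Igf2bp1 (-6.03 ± 0.79, edgeR adjusted p = 0.000198), whose adjusted p over the alternatives ranged from 1.43e-12 to 0.0888, the last with limma-voom. Prkaa2, the α2 catalytic subunit of AMPK, was 5.92-fold higher, at 20.2 ± 3.72 against 3.41 ± 1.46 CPM (SD; log2 fold change 2.56 ± 0.52 SE, edgeR adjusted p = 0.00729; alternatives 5.98e-05 to 0.0613, the last without adult replicate 3). Its counterpart Prkaa1 (0.17 ± 0.17), the kinase gene Mtor (-0.03 ± 0.22) and Tsc1 (0.17 ± 0.21) did not pass (edgeR adjusted p = 0.648, 0.963 and 0.738). Mafa, a transcription factor of mature β-cells, did not pass at 466 ± 78.9 against 412 ± 57.6 CPM (SD; log2 fold change 0.18 ± 0.17 SE, edgeR adjusted p = 0.627), with adjusted p between 0.0107 and 0.98 over the alternatives and a log2 fold change of 0.61 with the GC trend removed. The glucose transporter Slc2a2 (0.95 ± 0.32, adjusted p = 0.126; alternatives 6.01e-06 to 0.357, with 0.00528 without neonatal replicate 3a), Txnip (0.95 ± 0.36, adjusted p = 0.187; alternatives 0.0191, without adult replicate 2, to 0.419), Ldha (-1.49 ± 1.68, adjusted p = 0.703), Gcg (-0.12 ± 1.00, adjusted p = 0.972) and Sst (0.14 ± 0.40, adjusted p = 0.908) did not pass edgeR's test either. Lepr, Slc16a1, Ppargc1a and Aldh1a3 had too few counts to be tested.

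**Figure D2:**
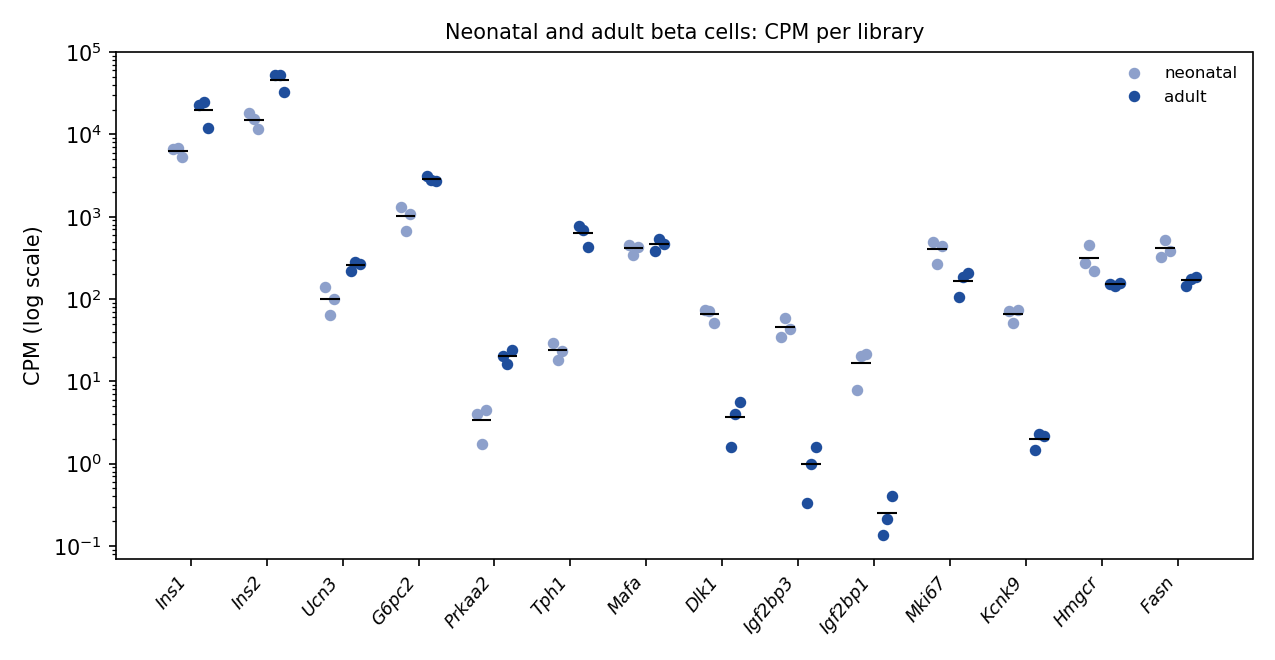
Points give CPM (log scale) of 14 genes in each neonatal (light) and adult (dark) β-cell library, n = 3 per group, with a line at each group's mean. Tph1 lay at 626.6 CPM on average in adult and 23.68 in neonatal cells, while Mafa lay at 465.8 and 411.8.

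Several of the fixed gene lists moved with age, each with a camera call at the preset correlation. Of 13 immature and progenitor endocrine genes, 8 fell and 5 were not called, and the called ones include Igf2bp3 and Dlk1. The immature gene list had a median of -2.11 (log2; camera adjusted p = 8.19e-15; adjusted p = 0.105 with an estimated correlation), and 9 of its genes passed adjusted over the list alone. Of 30 cell cycle genes, 10 fell and 20 were not called. The cell cycle list had a median of -1.29 (log2; camera adjusted p = 2.41e-11; adjusted p = 0.417 with an estimated correlation), and 14 of its genes passed adjusted over the list alone. The called cell cycle genes include the spindle protein Tpx2 (-1.93 ± 0.38) and the proliferation marker Mki67, 2.42-fold lower (log2 fold change -1.28 ± 0.27 SE, edgeR adjusted p = 0.0154; alternatives 5.79e-10 to 0.118, with 0.0502 without neonatal replicate 1 and 0.0561 without 3b). Of 24 genes of β-cell identity and maturity, 8 rose and 16 were not called, and the called ones include Ins1, Ins2, G6pc2 and the channel Trpm5 (1.35 ± 0.26). The β-cell identity list had a median of 0.26 (log2, 0.09 to 0.38 over the alternatives; camera adjusted p = 0.000223; adjusted p = 0.417 with an estimated correlation), and 10 higher and 3 lower genes passed adjusted over the list alone. Of 24 secretory granule and exocytosis genes, 6 rose, including Syt4 (1.91 ± 0.21) and the prohormone convertase chaperone Scg5 (0.88 ± 0.17), and 1 fell, the calcium sensor Syt7 (-0.80 ± 0.16, edgeR adjusted p = 0.0066, alternatives 7.28e-05 to 0.0581, the last without adult replicate 3). The secretory granule list had a median of 0.27 (log2, 0.11 to 0.43 over the alternatives; camera adjusted p = 0.0124; adjusted p = 0.426 with an estimated correlation), and 11 higher and 2 lower genes passed adjusted over the list alone. That list's adjusted p ranged from 0.00059 to 0.133 over the alternatives at the preset correlation, the highest with library size only.

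Some transcripts of the respiratory chain were higher in adult cells. Of 13 mitochondrially encoded genes, 6 rose, including mt-Cytb (1.19 ± 0.21) and mt-Co1 (0.93 ± 0.17; 0.71 and 0.53 with GC and length trends removed), and 7 were not called. The mitochondrially encoded list had a median of 0.93 (log2, 0.39 to 1.20 over the alternatives; camera adjusted p = 2.97e-07; adjusted p = 0.417 with an estimated correlation), and 10 of its genes passed adjusted over the list alone. These genes took 8.27%, 6.39% and 4.63% of counts in adult and 4.47%, 3.51% and 3.11% in neonatal libraries, so the groups did not overlap. Of 75 nuclear OXPHOS subunits, 6 rose, Uqcrq among them (1.32 ± 0.24), and 69 were not called. The nuclear OXPHOS list had a median of 0.30 (log2, 0.15 to 0.59 over the alternatives; camera adjusted p = 0.0018, alternatives at the preset correlation 2.61e-05 to 0.0739, the last with GC and length trends removed; adjusted p = 0.705 with an estimated correlation), and 6 of its genes passed adjusted over the list alone. Of 81 cytosolic ribosomal protein genes, whose many copies make counts uncertain, 2 rose, including Rpl26 (0.98 ± 0.19), and 79 were not called. The ribosomal protein list had a median of 0.39 (log2, 0.20 to 0.53 over the alternatives; camera adjusted p = 0.00211; adjusted p = 0.705 with an estimated correlation), and 2 of its genes passed adjusted over the list alone. Their adjusted p ranged from 1.43e-05 to 0.0627 over the alternatives at the preset correlation, and the call was lost without neonatal replicate 3b (0.0618). Of 25 cholesterol and fatty acid synthesis genes, 5 fell, including fatty acid synthase Fasn (-1.29 ± 0.19), and 20 were not called. The cholesterol and fatty acid list had a median of -0.59 (log2, -0.77 to -0.26 over the alternatives; camera adjusted p = 0.000679, alternatives at the preset correlation 4.75e-08 to 0.0974, the last without neonatal replicate 3a; adjusted p = 0.705 with an estimated correlation), and 8 of its genes passed adjusted over the list alone. Of 19 circadian clock genes, 6 fell, Per2 among them (-1.36 ± 0.23), and 13 were not called. The circadian clock list had a median of -0.43 (log2, -0.60 to -0.25 over the alternatives; camera adjusted p = 0.00655; adjusted p = 0.417 with an estimated correlation), and 6 of its genes passed adjusted over the list alone.

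Markers of other cells and of handling also differed between the ages. Of 12 duct cell markers, 5 were lower in adult cells and 7 were not called, and the called ones include the keratin Krt7 (-1.12 ± 0.18). The duct marker list had a median of -1.05 (log2; camera adjusted p = 0.000223; adjusted p = 0.179 with an estimated correlation), and 1 higher and 7 lower genes passed adjusted over the list alone. Of 11 markers of other islet endocrine cells, 2 were lower, including the retinol carrier Rbp4 (-1.10 ± 0.23, edgeR adjusted p = 0.00793, alternatives 2.24e-05 to 0.066, the last without adult replicate 2), and 9 were not called. The other endocrine marker list had a median of -1.10 (log2, -1.73 to -0.73 over the alternatives; camera adjusted p = 0.0105, alternatives at the preset correlation 0.000114 to 0.0775, the last without neonatal replicate 1; adjusted p = 0.705 with an estimated correlation), and 3 of its genes passed adjusted over the list alone. Of 21 immediate early and dissociation stress genes, 3 were lower, including Socs3 (-1.62 ± 0.30), and 18 were not called. The immediate early list had a median of -1.53 (log2, -1.94 to -0.83 over the alternatives; camera adjusted p = 0.000223; adjusted p = 0.705 with an estimated correlation), and 5 of its genes passed adjusted over the list alone. The other 16 lists with tested members were not called (camera adjusted p from 0.0763 to 0.938), and no erythroid marker had enough counts. Among these, 4 autophagy and lysosome genes rose, such as Gabarapl1 (1.27 ± 0.19) and 2 fatty acid oxidation genes fell, such as Cpt1a (-1.36 ± 0.23). Of 13 AMPK genes 1 rose (Prkaa2), of 4 neural markers 1 rose (Ngfr) and of 11 disallowed genes 1 fell (Oat, -2.44 ± 0.45). Some further calls were each lost when any of at least 2 libraries was left out. These were 1 glycolysis gene, 1 TCA cycle gene, 1 unfolded protein response gene (Ern1) and 1 ATF4 gene that rose. They were also 1 of 32 mTORC1 genes (Sesn2, also the 1 ATF4 gene that fell), 2 ER chaperones, 1 biogenesis regulator and 1 acinar marker that fell. The mesenchymal list was called without neonatal replicate 3a (median -2.06, camera adjusted p = 0.0316, alternatives at the preset correlation 0.0316 to 0.913). Autophagy was called with GC and length trends removed (0.22, 0.0463) and glycolysis with the GC trend removed (0.27, 0.0415). For the 23 antioxidant, 7 immune, 13 mesenchymal and 7 endothelial genes edgeR called 0, with 3, 2, 0 and 0 at an unadjusted p under 0.05. DESeq2 called 0 in each, and limma-voom called 2 antioxidant genes and 0 in the others. Median, mean and test differed in sign for the immune, endothelial, neural, AMPK, fatty acid oxidation and ER chaperone lists.

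The second comparison addresses what loss of TSC1, the partner of TSC2 in the complex that restrains mTORC1, does to islets. Tsc1 (ENSMUSG00000026812) itself read 31 and 34.45 CPM in the islets labelled TSC1 KO and 25.12 and 54.14 CPM in the controls (log2 fold change -0.28 ± 0.38 SE, edgeR adjusted p = 0.638), so it did not separate the groups. Its adjusted p ranged from 0.0415, without RC control replicate 1, to 0.843. A count over the whole gene in whole islets cannot show whether the targeted part was removed in β-cells, and every direction below follows the labels. Ins2 was 33.4-fold lower in the knockout islets, at 4849 ± 905 against 162000 ± 17240 CPM (SD, n = 2 each; log2 fold change -5.06 ± 0.52 SE, edgeR adjusted p = 0.0105), and Ins1 12.6-fold lower (log2 fold change -3.66 ± 0.46 SE, edgeR adjusted p = 0.0118). Ucn3 was 6.24-fold lower (log2 fold change -2.64 ± 0.31 SE, edgeR adjusted p = 0.0109), Mafa 5.20-fold lower (log2 fold change -2.38 ± 0.38 SE, edgeR adjusted p = 0.0169) and Slc30a8, the zinc transporter of insulin granules, 11.05-fold lower (log2 fold change -3.47 ± 0.36 SE, edgeR adjusted p = 0.0106). The mitochondrially encoded complex I subunit mt-Nd5 was 8.62-fold higher (log2 fold change 3.11 ± 0.46 SE, edgeR adjusted p = 0.0146) and Ppargc1a, a coactivator of mitochondrial biogenesis, 10.5-fold higher (log2 fold change 3.39 ± 0.48 SE, edgeR adjusted p = 0.0135).

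In the islets labelled TSC1 KO, 1252 of 14515 genes were called higher and 1451 lower, 1050 and 1269 of them by at least 2-fold. With library size as the only scaling the split was 756 higher and 1961 lower. The median of all genes moved to -0.25. Without TSC1 KO replicate 1 or 2, edgeR called 0 genes (3535 and 3061 at an unadjusted p under 0.05; lowest adjusted p = 0.0892 and 0.148). There limma-voom called 0 (3061 and 2953) and DESeq2 called 844 and 555, so every edgeR call in this comparison needs both knockout libraries. Without RC control replicate 1 edgeR called 2156 higher and 1859 lower. Among the 10 largest rises were the stomach genes Gkn3 (7.88 ± 1.04), Pgc (6.08 ± 0.84) and Muc6 (5.93 ± 0.57) and the secreted glycoprotein Stc2 (4.52 ± 0.52) (edgeR adjusted p between 0.0105 and 0.0174), with Gkn3 losing its call without either control (alternatives 0.00046 to 0.148). Gkn3 and Pgc had 0 counts in RC control replicate 2, so the size of their folds rests on replicate 1 (0.7899 and 1.896 CPM). Among the largest falls were the glucagon receptor Gcgr (-5.03 ± 0.36) and the ER degradation component Derl3 (-4.84 ± 0.38; edgeR adjusted p = 0.0105 for both). Lepr, the leptin receptor, was 6.89-fold higher (log2 fold change 2.78 ± 0.43 SE, edgeR adjusted p = 0.0177). Prkaa1 (-0.43 ± 0.20, adjusted p = 0.177), Mtor (0.12 ± 0.26, adjusted p = 0.773), Txnip (0.83 ± 0.32, adjusted p = 0.12), Slc16a1 (0.72 ± 0.57, adjusted p = 0.403), Mki67 (0.20 ± 0.37, adjusted p = 0.74) and Sst (-0.67 ± 0.57, adjusted p = 0.44) did not pass edgeR's test. Nor did Slc2a2 (-1.10 ± 0.35, adjusted p = 0.0788; alternatives 0.00557 to 0.356), Prkaa2 (0.95 ± 0.28, adjusted p = 0.0627; alternatives 0.0417 to 0.299) and Ldha (0.90 ± 0.45, adjusted p = 0.212; alternatives 0.00172 to 0.484). Each of these 3 passed without RC control replicate 1, at its lowest p. Aldh1a3 was not tested, with 30 and 2 counts in the controls and 7 and 1 in the knockouts.

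Most genes of β-cell function were lower in the islets labelled TSC1 KO. Of 24 genes of β-cell identity and maturity, 21 fell and 3 were not called. The β-cell identity list had a median of -2.89 (log2; camera adjusted p = 8.73e-30; adjusted p = 0.697 with an estimated correlation), and 23 of its genes passed adjusted over the list alone. Of 24 secretory granule and exocytosis genes, 20 fell and 4 were not called, and the called ones include the vesicle proteins Syt4 (-3.74 ± 0.35) and Syt13 (-3.41 ± 0.42). The secretory granule list had a median of -2.37 (log2; camera adjusted p = 1.23e-16; adjusted p = 0.697 with an estimated correlation), and 21 of its genes passed adjusted over the list alone. Of 20 ER chaperones and unfolded protein response genes, 12 fell and 8 were not called, and the called ones include Sdf2l1 (-3.75 ± 0.24), Manf (-2.46 ± 0.22), Hyou1 (-2.14 ± 0.31) and Dnajb9 (-2.09 ± 0.23). The ER chaperone list had a median of -1.11 (log2; camera adjusted p = 1.72e-09; adjusted p = 0.697 with an estimated correlation), and 16 of its genes passed adjusted over the list alone. Of 23 ATF4 and amino acid response genes, 7 fell and 16 were not called, and the called ones include the glutathione-degrading enzyme Chac1 (-2.94 ± 0.33), the amino acid transporter Slc7a5 (-2.49 ± 0.28) and asparagine synthetase Asns (-1.53 ± 0.20). The ATF4 response list had a median of -0.60 (log2; camera adjusted p = 0.00743; adjusted p = 0.697 with an estimated correlation), and 8 of its genes passed adjusted over the list alone. Some other islet hormones also fell, while Sst did not pass. Of 11 markers of other islet endocrine cells, 8 fell, 1 rose and 2 were not called. The other endocrine marker list had a median of -2.21 (log2; camera adjusted p = 0.000974; adjusted p = 0.697 with an estimated correlation), and 8 lower and 1 higher genes passed adjusted over the list alone. The pancreatic polypeptide gene Ppy (-3.36 ± 0.62), Pyy (-2.75 ± 0.57) and the glucagon gene Gcg (log2 fold change -2.56 ± 0.65 SE, edgeR adjusted p = 0.0447; alternatives 2.78e-05 to 0.217, with 0.0677 without RC control replicate 2) were among those that fell, and mitochondrial transcripts took 39.77% and 46.83% of counts in the same libraries.

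Other groups were higher in the islets labelled TSC1 KO. Of 13 mitochondrially encoded genes, 12 rose and 1 was not called. Of 73 nuclear OXPHOS subunits 10 fell and 63 were not called. The mitochondrially encoded list had a median of 2.26 (log2; camera adjusted p = 1.81e-11; adjusted p = 0.811 with an estimated correlation), and 13 of its genes passed adjusted over the list alone. The nuclear OXPHOS list had a median of -0.38 (log2, -0.63 to -0.18 over the alternatives; camera adjusted p = 0.00544, alternatives at the preset correlation 5.36e-05 to 0.121, the last without RC control replicate 1; adjusted p = 0.894 with an estimated correlation), and 6 of its genes passed adjusted over the list alone. Of 22 genes usually kept silent in β-cells (disallowed genes), 9 rose and 13 were not called, and the called ones include the chemokine Cxcl12 (2.53 ± 0.34), the repressor Rest (2.39 ± 0.30) and Smad3 (2.15 ± 0.24). The disallowed gene list had a median of 1.73 (log2; camera adjusted p = 1.89e-09; adjusted p = 0.857 with an estimated correlation), and 15 of its genes passed adjusted over the list alone. Some endothelial and duct markers rose in the same libraries. Counts of whole islets do not show whether the disallowed genes rose in β-cells or came from other cells. Of 14 endothelial markers, 6 rose and 8 were not called, and the called ones include Tek (2.21 ± 0.22) and Cdh5 (1.54 ± 0.28). The endothelial marker list had a median of 1.12 (log2; camera adjusted p = 0.000115; adjusted p = 0.857 with an estimated correlation), and 8 of its genes passed adjusted over the list alone. Of 14 duct markers, 4 rose, including Bicc1 (3.16 ± 0.56), and 10 were not called. The duct marker list had a median of 1.71 (log2, 1.20 to 3.39 over the alternatives; camera adjusted p = 0.00042; adjusted p = 0.857 with an estimated correlation), and 4 of its genes passed adjusted over the list alone. Of 18 mesenchymal markers 1 rose, Fbn1 (2.87 ± 0.44), and 17 were not called. The mesenchymal marker list had a median of 0.97 (log2, 0.69 to 2.46 over the alternatives; camera adjusted p = 0.00544; adjusted p = 0.857 with an estimated correlation), and 1 of its genes passed adjusted over the list alone. Of 21 immediate early genes edgeR called 0 (6 at an unadjusted p under 0.05; DESeq2 called 6 and limma-voom 1). The immediate early list had a median of 1.02 (log2, 0.54 to 1.64 over the alternatives; camera adjusted p = 0.0101; adjusted p = 0.857 with an estimated correlation). Both the mesenchymal and the immediate early list lost the camera call without RC control replicate 2 (adjusted p = 0.171 each, the highest over the alternatives at the preset correlation, with 3.51e-08 and 1.42e-05 the lowest).

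The other 17 lists were not called in the islets labelled TSC1 KO (camera adjusted p from 0.14 to 0.924). The erythroid list was called with the replicate number as a block (median 1.24, camera adjusted p = 0.00727). Leaving out a library also gave it a call (median 2.01 without RC control replicate 1, 1.42 without TSC1 KO replicate 2). The ribosomal list was called without RC control replicate 2 (-0.33). Leaving out a library gave a call to the acinar list (-0.94, without TSC1 KO replicate 1) and the neural list (0.99, without TSC1 KO replicate 2) as well. Of 34 mTORC1 components and regulators, 5 fell, including folliculin (Flcn, -1.26 ± 0.27) and Rragb (-1.62 ± 0.30), and 29 were not called. For the 13 AMPK genes edgeR called 0, with 3 at an unadjusted p under 0.05. For the 81 ribosomal, 28 acinar and 5 erythroid genes it called 0, with 5, 3 and 0, and DESeq2 and limma-voom called 0 in each of these lists. Cholesterol and fatty acid synthesis had 2 higher and 7 lower of 26, with citrate lyase Acly at -1.48 ± 0.32. Fatty acid oxidation had 2 higher, Cpt1a at 1.14 ± 0.24 among them, and 1 lower, Hadh (-1.61 ± 0.30). Pyruvate carboxylase Pcx (-2.61 ± 0.27) was the 1 TCA cycle gene that fell. Of 23 antioxidant genes 3 rose, including Nqo1 (1.74 ± 0.32), and 2 fell. Of 25 cell cycle genes 3 rose, including Mcm6 (1.41 ± 0.25). Of 16 biogenesis regulators 2 rose, Ppargc1a among them. Glycolysis had 1 higher (Slc2a1) and 1 lower, immature genes 1 higher (Sox4) and 1 lower (Pyy). Autophagy had 2 lower (Hexa and Atp6v0d1), the clock 1 lower (Cry2), immune markers 1 lower (C1qa, -1.37 ± 0.20) and neural markers 1 higher (Erbb3). The immune list's median differed in sign from its mean and test.

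The third comparison addresses the islets of a diabetes model. Db is the usual name of a mutation of the leptin receptor gene Lepr, for which the libraries held 1 and 4 counts in Db islets and 11 and 2 in the controls, too few to test or to check the labels. Aldh1a3 (ENSMUSG00000015134), a retinaldehyde dehydrogenase that is low in healthy mature β-cells, was 195-fold higher in Db islets, at 104 ± 34.9 against 0.514 ± 0.182 CPM (SD, n = 2 each; log2 fold change 7.61 ± 0.37 SE, edgeR adjusted p = 3.04e-14). The glucose transporter Slc2a2 was 16.9-fold lower (log2 fold change -4.08 ± 0.24 SE, edgeR adjusted p = 2.76e-13), Mafa 7.69-fold lower (log2 fold change -2.94 ± 0.26 SE, edgeR adjusted p = 3.3e-09), Slc30a8 6.03-fold lower (log2 fold change -2.59 ± 0.22 SE, edgeR adjusted p = 2.12e-10) and Ucn3 2.23-fold lower (log2 fold change -1.16 ± 0.21 SE, edgeR adjusted p = 6.82e-05). The gut hormone gene Gast had 841 counts in Db libraries and 0 in controls, which makes it at least 124-fold higher (edgeR adjusted p = 2.84e-11). The related Cck was 351-fold higher (log2 fold change 8.46 ± 0.46 SE, edgeR adjusted p = 4.34e-10), a size resting on BKS control replicate 1, as replicate 2 had 0 counts. Ins2 was 1.9-fold lower (log2 fold change -0.93 ± 0.33 SE, edgeR adjusted p = 0.0209), with adjusted p between 0.000186 and 0.314 over the alternatives. That call was lost with library size only (0.233) and without BKS control replicate 2 (0.0644), Db replicate 1 (0.137) or Db replicate 2 (0.314). Ins1, at -0.58 ± 0.31, did not pass (edgeR adjusted p = 0.118; alternatives 0.00638, without BKS control replicate 1, to 0.684).

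In Db islets 3488 of 14369 genes were called higher and 3431 lower, 2023 and 2132 of them by at least 2-fold. With library size as the only scaling the split was 3983 higher and 1562 lower, the median of all genes moving to 0.29, and without Db replicate 2 1952 genes were called lower. Fold changes rose with GC content across genes (Spearman 0.397, genes not being independent replicates), and with the GC trend removed 4552 of the 6919 calls (65.8%) remained and 117 had a fold change of the opposite sign. Among the 10 largest rises were C1qtnf1, a secreted C1q-related protein (6.47 ± 0.28), the metallothionein Mt3 (4.995 ± 0.31) and Zcchc12 (4.62 ± 0.32; edgeR adjusted p between 2.76e-16 and 5.64e-12), and the bile acid receptor Gpbar1, whose normalised ratio was 226 (counting interval 40.4 to 8950) from 511 counts against 1. Among the largest falls were the imprinted gene Nnat (-4.72 ± 0.26), the activity-induced factor Npas4 (-4.60 ± 0.29), the potassium channel Kcnj12 (-4.68 ± 0.35), the cytochrome oxidase subunit Cox6a2 (-3.52 ± 0.24) and the GABA-synthesising enzyme Gad1 (-3.26 ± 0.25; edgeR adjusted p between 7.2e-13 and 2.5e-10). Sst was 2.97-fold higher (log2 fold change 1.57 ± 0.24 SE, edgeR adjusted p = 7.25e-06), Txnip, an inhibitor of thioredoxin induced by glucose, 2.98-fold higher (log2 fold change 1.58 ± 0.23 SE, edgeR adjusted p = 6.11e-06), and Mki67 3.98-fold lower (log2 fold change -1.99 ± 0.28 SE, edgeR adjusted p = 2.02e-06). Mtor (0.78 ± 0.23, adjusted p = 0.00611; alternatives 0.000303 to 0.374) was called higher and Prkaa1 (-0.96 ± 0.24, adjusted p = 0.00147; alternatives 0.00106 to 0.544) lower by edgeR, and both calls were lost with the GC trend removed (0.33 and -0.20) and without Db replicate 2 (0.118 and 0.0615). Prkaa2 (-0.48 ± 0.44, adjusted p = 0.382), Tsc1 (0.10 ± 0.24, adjusted p = 0.74) and Ldha (-0.35 ± 0.29, adjusted p = 0.324) did not pass edgeR's test. Neither did Gcg (0.49 ± 0.30, adjusted p = 0.193; alternatives 1.08e-06 to 0.886), which passed without BKS control replicate 2, and Slc16a1 and Ppargc1a had too few counts.

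**Figure D3:**
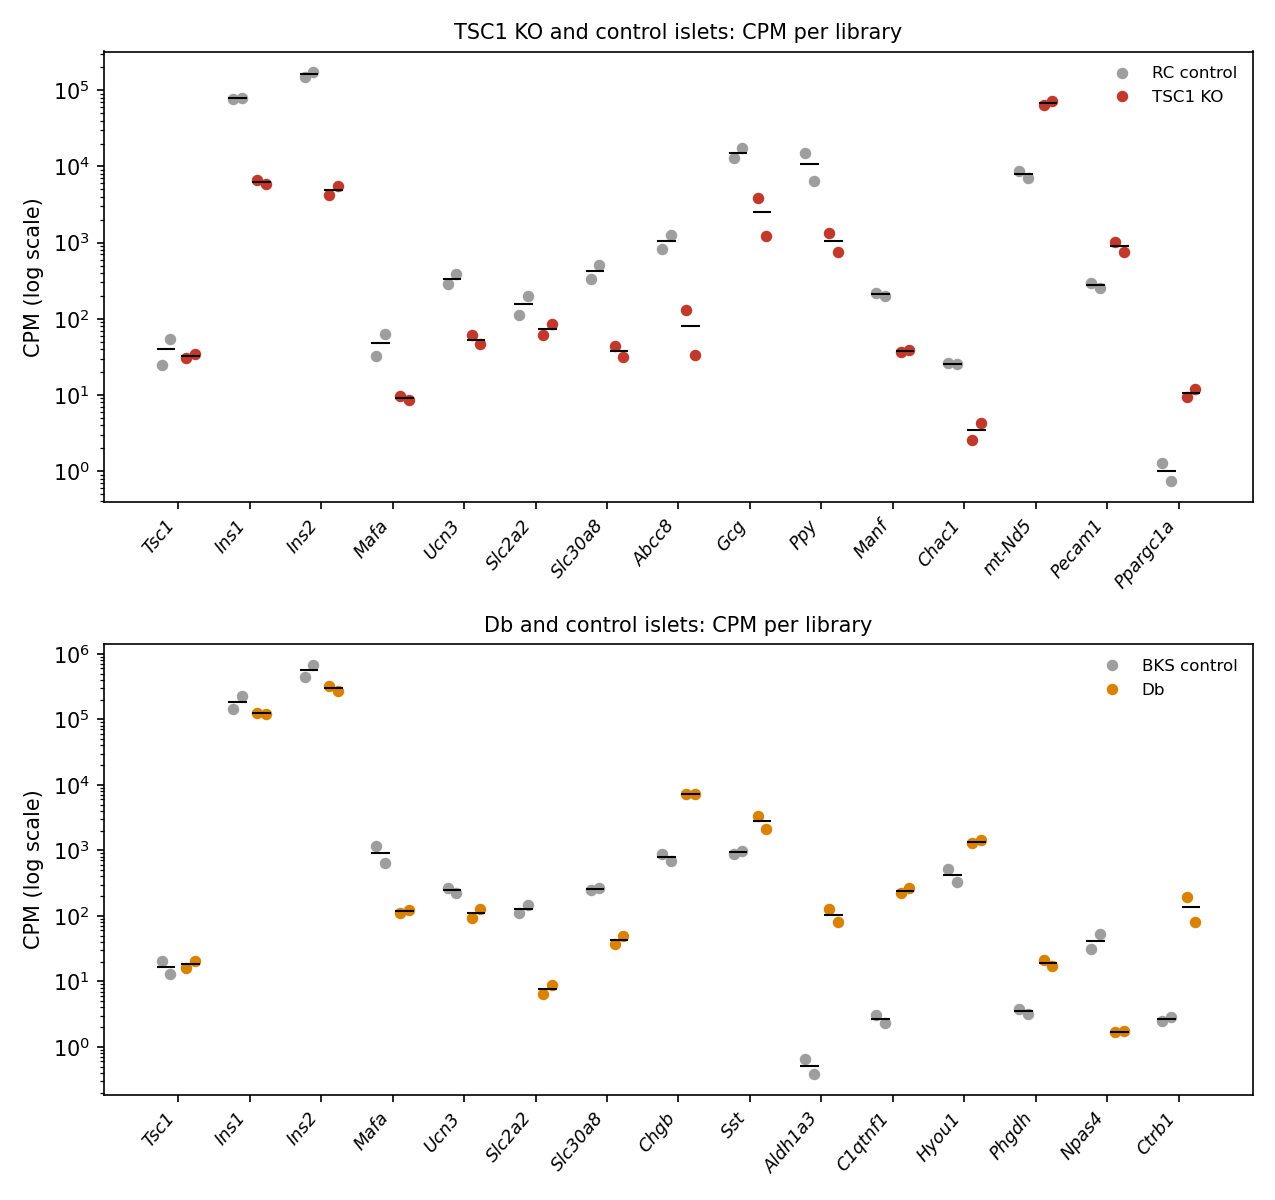
Points give CPM (log scale) in each library of the TSC1 KO and control islets (upper panel, 15 genes) and the Db and control islets (lower panel, 15 genes), n = 2 per group, with a line at each group's mean. Tsc1 overlapped between groups in both panels, Slc2a2 averaged 7.545 CPM in Db and 128.2 in control islets, and Ins2 averaged 4849 CPM in TSC1 KO and 162000 in control islets.

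Among the lists called in Db islets, secretory granule, ATF4 and ER chaperones moved up. The lists of β-cell identity, cell cycle and immediate early genes moved down, and in each list some members were not called. Of 24 secretory granule and exocytosis genes, 14 rose, 1 fell and 9 were not called, and the called ones include the granule proteins Chgb (3.20 ± 0.26), Vgf (3.10 ± 0.23) and Ptprn (2.41 ± 0.24). The secretory granule list had a median of 0.72 (log2; camera adjusted p = 8.63e-05; adjusted p = 0.607 with an estimated correlation), and 14 higher and 1 lower genes passed adjusted over the list alone. Of 22 ATF4 and amino acid response genes, 15 rose, 3 fell and 4 were not called, and the called ones include the serine synthesis enzymes Phgdh (2.45 ± 0.28) and Psph (2.29 ± 0.34) and the mitochondrial folate enzyme Aldh1l2 (2.09 ± 0.29). The ATF4 response list had a median of 0.97 (log2; camera adjusted p = 0.000825; adjusted p = 0.607 with an estimated correlation), and 15 higher and 3 lower genes passed adjusted over the list alone. Of 20 ER chaperones and unfolded protein response genes, 11 rose and 9 were not called, and the called ones include Creld2 (1.88 ± 0.21) and Hyou1 (1.66 ± 0.24). The ER chaperone list had a median of 0.61 (log2, 0.49 to 0.92 over the alternatives; camera adjusted p = 0.0317, alternatives at the preset correlation 0.00171 to 0.0551, the last without Db replicate 1; adjusted p = 0.607 with an estimated correlation), and 12 of its genes passed adjusted over the list alone. Of 24 genes of β-cell identity and maturity, 12 fell, 5 rose and 7 were not called, and the called ones include Trpm5 (-2.69 ± 0.22). The β-cell identity list had a median of -0.61 (log2, -0.64 to -0.29 over the alternatives; camera adjusted p = 0.0015; adjusted p = 0.607 with an estimated correlation), and 12 lower and 5 higher genes passed adjusted over the list alone. Of 14 immature and progenitor endocrine genes, 6 rose, including Aldh1a3, Gast and H19 (2.44 ± 0.56), 3 fell, including Npy (-3.05 ± 0.67), and 5 were not called. The immature gene list had a median of 0.53 (log2, 0.40 to 0.89 over the alternatives; camera adjusted p = 0.028, alternatives at the preset correlation 0.00561 to 0.189; adjusted p = 0.607 with an estimated correlation), and 7 higher and 3 lower genes passed adjusted over the list alone. This call was lost with the GC trend removed (0.0975) and without BKS control replicate 1 (0.189), BKS control replicate 2 (0.0851) or Db replicate 1 (0.0988). Of 29 cell cycle genes, 12 fell, 2 rose and 15 were not called, and the called ones include Top2a (-3.003 ± 0.28) and Ccna2 (-2.07 ± 0.28). The cell cycle list had a median of -0.48 (log2, -0.79 to -0.13 over the alternatives; camera adjusted p = 0.00619; adjusted p = 0.607 with an estimated correlation), and 12 lower and 2 higher genes passed adjusted over the list alone. Of 21 immediate early genes, 13 fell and 8 were not called, and the called ones include the heat shock genes Hspa1a (-2.50 ± 0.23) and Hspa1b (-2.27 ± 0.24), near-identical copies. The immediate early list had a median of -1.56 (log2, -1.80 to -1.02 over the alternatives; camera adjusted p = 6.86e-06; adjusted p = 0.607 with an estimated correlation), and 13 of its genes passed adjusted over the list alone.

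Most acinar markers were higher in the same Db libraries. Of 20 acinar markers, 14 rose, 1 fell and 5 were not called. The acinar marker list had a median of 1.96, unchanged with genes at 0 set to their bound (log2; camera adjusted p = 1.41e-05; adjusted p = 0.607 with an estimated correlation), and 15 higher and 1 lower genes passed adjusted over the list alone. Ctrb1, a chymotrypsinogen, read 138 ± 82.2 against 2.64 ± 0.255 CPM (SD; log2 fold change 5.71 ± 0.60 SE, edgeR adjusted p = 0.00104), and the trypsinogen Prss1, a gene with close copies, had 160 counts against 0, at least 23.6-fold higher (edgeR adjusted p = 0.000836). The other 21 lists were not called (camera adjusted p from 0.0801 to 0.987). Of 6 erythroid markers 4 were higher (median 1.71). Settings that called this list include the replicate block (1.69, camera adjusted p = 0.0468), a filter at 1 CPM (1.99, 0.00909) and library size only (2.02, 0.049). The list was also called without BKS control replicate 1 (2.11), Db replicate 1 (2.22) or Db replicate 2 (1.48). The mitochondrially encoded list, with a median of -1.43, ran from -2.03 without BKS control replicate 1 (camera adjusted p = 5.24e-17) to 0.17 without BKS control replicate 2 (0.966). It was also called without Db replicate 1 (0.00295). Mesenchymal markers were called with the replicate block (median 0.554, camera adjusted p = 0.049) and a filter at 1 CPM (0.557, 0.0479). They were also called without BKS control replicate 2 (0.595) or Db replicate 1 (0.655). Calls also appeared for other endocrine markers (0.662 without BKS control replicate 2) and glycolysis (0.485 without BKS control replicate 1). Immune markers were called with the GC trend removed (-0.57, 0.00267) and the mitochondrially encoded list with library size only (-1.01, 0.000471). Without a filter on low counts, nuclear OXPHOS (0.0141), ribosomal (0.0231), glycolysis (0.0217), mesenchymal (0.00585) and erythroid genes (0.0248) were called. Of 33 mTORC1 components and regulators, 8 rose, including Lamtor2 (2.46 ± 0.22) and Eif4ebp1 (1.68 ± 0.25), 5 fell, including Sesn1 (-1.30 ± 0.28), and 20 were not called. AMPK genes had 1 higher and 4 lower of 13. Of 73 nuclear OXPHOS subunits 31 rose, such as Ndufa1 (2.44 ± 0.23), and 17 fell, such as Ndufb2 (-1.71 ± 0.26). Of 11 mitochondrially encoded genes 1 fell, mt-Co1 (log2 fold change -1.56 ± 0.40 SE, edgeR adjusted p = 0.0136; alternatives 2.44e-18 to 0.064, the last with GC and length trends removed, at -0.70). Ribosomal protein genes had 26 higher and 19 lower of 81, glycolysis 6 higher of 16, such as Aldoa (1.47 ± 0.21), a list whose median turned negative with the GC trend removed (-0.12). Antioxidant genes had 8 higher, such as Hmox1 (3.28 ± 0.42, with controls at 1.606 and 0.2567 CPM), and 4 lower, such as Nqo1 (-3.58 ± 0.48), of 23. Autophagy and lysosome genes had 9 higher and 7 lower of 28, TCA cycle genes 8 and 5 of 23. Fatty acid oxidation had 5 and 7 of 19, cholesterol and fatty acid synthesis 7 and 4 of 24, biogenesis regulators 5 and 4 of 16, disallowed genes 4 and 5 of 18 and clock genes 2 and 5 of 18. Markers of mesenchymal cells had 8 higher and 2 lower of 18, endothelial 6 and 5 of 14, other endocrine 3 and 2 of 11, with Ttr at 2.804 ± 0.30, duct 4 and 4 of 12 and neural 1 and 2 of 6, while 6 of 16 immune markers were lower. Median, mean and test differed in sign for the TCA cycle, duct and endothelial lists.

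The series title links maturation with diabetes, so the age signature was followed into the islets. The 200 genes higher in adult β-cells had a median log2 fold change of -0.91 in the islets labelled TSC1 KO, with 79 lower and 14 higher (camera adjusted p = 3.44e-12, and adjusted p = 0.305 with an estimated correlation and 0.0651 with fry, which tests against no change), and of -0.16 in Db islets, with 61 lower and 49 higher (camera adjusted p = 0.504). The latter median turned positive with library size only (0.17) and with the GC trend removed (0.08). In the islets labelled TSC1 KO, the β-cell identity (median -2.89) and secretory granule lists (-2.37) fell further than the adult-high signature. That signature was chosen in β-cells, so a general fall of endocrine transcripts in whole islets could also lower it. The 2 were not told apart. The 200 genes higher in neonatal β-cells had a median of 0.15 in the islets labelled TSC1 KO (camera adjusted p = 0.577, with a mean of -0.05) and of 0.46 in Db islets, with 93 higher and 30 lower (camera adjusted p = 0.00235; adjusted p = 0.131 with an estimated correlation, 0.00794 with fry, and 0.387 with the GC trend removed, where the median was 0.15). Over the alternatives, that adjusted p ranged from 0.00138 to 0.387. Across the 13395 genes tested in both islet comparisons, fold changes had a Spearman correlation of 0 and a Pearson correlation of 0.02. Genes higher in both numbered 267, against 265 from independent lists (odds ratio 1.01, 95% interval 0.872 to 1.17, Fisher's exact p = 0.883), and genes lower in both 374 against 349 (1.11, 0.976 to 1.26, Fisher's exact p = 0.104). The latter overlap passed with the GC trend removed (1.63, Fisher's exact p = 2.2e-13) and with DESeq2 (1.42, 1.51e-06). It also passed without RC control replicate 1 (1.12, 0.0466), BKS control replicate 1 (1.26, 0.000435), BKS control replicate 2 (1.19, 0.0106) or Db replicate 2 (1.6, 2.19e-10). Genes lower in the islets labelled TSC1 KO and higher in Db islets numbered 439 against 344 (1.46, 1.29 to 1.65, Fisher's exact p = 1.29e-09). Fisher's test takes genes as independent, which they are not, so these p-values and intervals do not measure the spread between libraries. Among the 10 genes called in both with the largest mean change, Stc2 rose in both (4.52 ± 0.52 and 4.44 ± 0.54, SE), Npas4 fell in both (-3.51 ± 0.29 and -4.60 ± 0.29) and Derl3 fell in the knockout and rose in Db islets (-4.84 ± 0.38 and 2.50 ± 0.23).

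**Figure D4:**
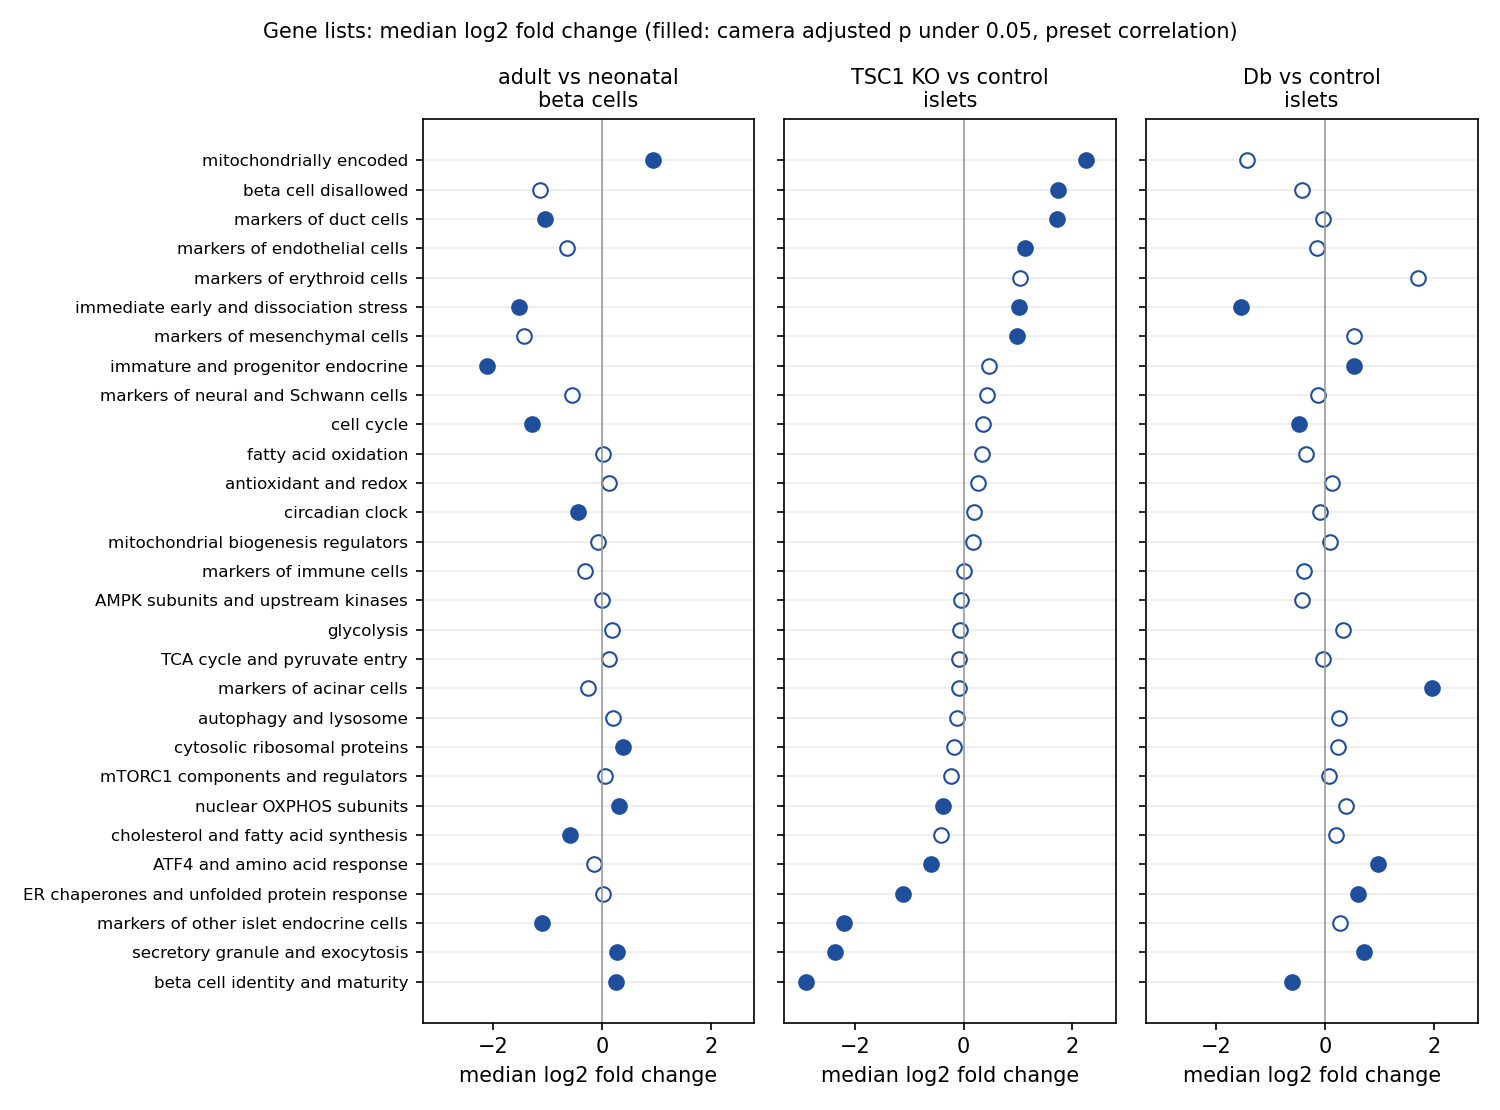
Points give the median log2 fold change of each of the 29 gene lists in the 3 comparisons (x axis, log2), filled where camera with the preset correlation gave an adjusted p under the threshold. The β-cell identity list lay at 0.26, -2.89 and -0.61, and the secretory granule list at 0.27, -2.37 and 0.72, in the age, TSC1 KO and Db comparisons.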

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

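The tests of a lower share of β-cells and of endocrine cells, of the GC trend and of depth, and those leaving out insulin, mitochondrial or marker genes, were chosen after the results were seen, and so was the rule that a test moving fold changes by under 0.1 of a standard error decides nothing. The TSC1 KO and Db effects differed by an interaction test over the 8 islet libraries for 4988 of 15702 genes (edgeR, Benjamini-Hochberg adjusted), with 2066 more positive and 2922 more negative in the TSC1 KO contrast. The contrasts also differ in age and table, so each difference belongs to the pair of experiments. Differences (TSC1 KO minus Db, log2) were -4.22 for Ins2, -3.16 for Ins1, -1.57 for Ucn3, 2.89 for Slc2a2, -3.13 for Gcg, -2.33 for Sst and 2.09 for Mki67. Values of -8.86 for Aldh1a3, 5.15 for Lepr and 3.48 for Ppargc1a rest on a contrast in which the gene had too few counts for its own fit. Lists are given where camera on the interaction passed at the preset correlation. An estimated correlation and left-out libraries were not tried for it. Median differences were 3.94 for mitochondrially encoded genes, 2.28 for duct markers, 2.17 for disallowed genes, 2.13 for immediate early genes, 1.12 for endothelial markers and 0.88 for the cell cycle. They were -3.08 for other endocrine markers, -2.70 for secretory granule genes, -2.43 for β-cell identity, -1.73 for acinar markers, -1.65 for the ATF4 list, -1.64 for ER chaperones and -0.63 for nuclear OXPHOS subunits.

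The fall of endocrine genes in islets labelled TSC1 KO may come from fewer endocrine cells in the sample, but markers of other cells moved unequally. Medians were 1.12 for endothelial, 1.71 for duct, 0.97 for mesenchymal, 1.04 for erythroid and 0.43 for neural markers. They were -0.09 for acinar (-0.94 without TSC1 KO replicate 1) and 0.01 for immune markers. A loss of β-cells alone would have left markers of other endocrine cells unchanged or raised, and their median was -2.208. A lower share of all endocrine cells would move the β-cell identity genes by a common factor only if no other cells made them. They ran from -5.06 (Ins2) to -1.11 (Slc2a2), with heterogeneity of 4.34 per degree of freedom (Cochran's Q = 99.7 over 24 genes). Q takes genes as independent, while their estimated correlation was 0.783, and expression in other cells was not tested. The falls were thus unequal, but Q cannot decide how much of them a common loss accounts for. RNA integrity and effects within cells were not tested. Leaving out mitochondrially encoded genes kept 100% of the 21 calls in the β-cell identity list but moved fold changes by only 0.0683 of their standard error, so it decides nothing about their share of reads.

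The number and size of changes in Db islets could owe something to library properties. Thinning all libraries to the smallest total kept 89.5% of the 6919 calls, so unequal totals alone do not explain most of them. Thinning does not address other differences between the deeper and the shallower libraries. Removing the GC trend kept 65.8%, between the values set for and against, and turned the sign of 117 calls. For the calls that were lost, a GC bias and a change of GC-rich genes cannot be told apart. Leaving out Ins1 and Ins2 kept 98.5% but moved fold changes by only 0.0785 of their standard error, so the bound set for it was not informative. The Db label itself is confounded with any difference in preparation between the groups.

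The changes between neonatal and adult β-cells were set against the other ways of splitting the 6 libraries. Only 1 of 10 splits, the real one, called as many as 999 genes, and the highest of the others called 0 with edgeR (up to 461 at an unadjusted p under 0.05); 10 splits are too few for a share under 0.05. Removing the GC trend kept 66.5% of calls, so GC content may contribute, and for the calls that were lost it cannot be told apart from age. Leaving out marker genes of other cell types kept 100% of the 990 other calls, but moved fold changes by only 0.00456 of their standard error, so it decides nothing about admixed cells. Age itself remains an open explanation.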

How the results depend on the processing

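The GC settings, thinning, leaving out genes, and DESeq2 for the agreement and with libraries left out were chosen after seeing the data. Over all settings, 179 of 216 summary values held, 10 were stronger, 25 weaker and 2 reversed. Gene lists gave 1493, 38, 76 and 1, and named genes 5924, 38, 580 and 0. A test result without a call in either fit counted as held even where its sign changed. The adult-high signature in Db islets did so, from -0.156 to 0.083 with the GC trend removed. Settings that hardly moved fold changes, such as leaving out marker genes, are counted too. Counts of called genes moved most. For age, library size only gave 321 higher and 872 lower, DESeq2 747 and 842, a log2 change of at least 1 gave 307 higher, and leaving out a library 217 to 669 higher and 188 to 711 lower. For TSC1 KO, library size only gave 756 higher, and leaving out a library 0 to 2156 higher and 0 to 1859 lower. For Db, library size only gave 1562 lower, a change of at least 1 gave 2023 and 2132, and leaving out a library 1952 to 3156 lower. In the lone-library fits the single sample is assumed to vary like the other group. The smaller counts at a log2 change of at least 1 follow from that limit; otherwise the cause was not tested.

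The adult-high signature in TSC1 KO (median -0.912) lost its call with an estimated correlation and with fry, which tests against no change. Both settings change the test only and cannot move the median. The neonatal-high signature in Db lost its call with an estimated correlation (median 0.457) and with the GC trend removed (0.151). The odds ratio of genes higher in both islet models fell below 1 with the GC trend removed (0.831, Fisher's exact p = 0.0213, with 0.0213 to 0.905 over the alternatives that left calls in both; without either TSC1 KO library edgeR left none in the knockout comparison) and over left-out libraries ranged from 0.845 to 1.08, with 0.845 without BKS control replicate 1. For genes lower in both it was 1.63 with the GC trend removed, 1.42 with DESeq2 and 1.1 to 1.6 without a library, and passed in all of these except without RC control replicate 2 or Db replicate 1 (Fisher's exact p = 2.2e-13 to 0.179 over the alternatives with calls). The ATF4 list in the age comparison, at -0.149, ranged from -0.568 to 0.534 over left-out libraries, the last without neonatal replicate 3a (camera adjusted p = 0.000401; over the alternatives, 0.000401 to 0.967, the last with an estimated correlation). The cause was not tested. Of the list calls, an estimated correlation kept 0 in each comparison. The estimates for called lists ran from -0.043 (ER chaperones, Db) to 0.947 (mitochondrially encoded genes, TSC1 KO). Calls were thus lost even below the preset of 0.01, and the few residual degrees of freedom also weaken that test. Fry kept 2 of 12 for age, 0 of 12 for TSC1 KO and 4 of 8 for Db. Fry also passed lists that camera did not call. These were autophagy and lysosome for age (fry adjusted p = 0.0418), and nuclear OXPHOS (0.0446) and immune markers (0.0304) for Db.

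No paired analysis was possible because the neonatal columns repeat number 3 and lack number 2. For the islets the replicate number as a block gave 727 higher and 921 lower for TSC1 KO (614 and 739 with the GC trend also removed), and 3369 and 3245 for Db. Deviations of same-numbered libraries correlated at -0.05 and -0.04, so no strong shared effect was seen. With 2 libraries per group this cannot show whether equal numbers mark paired samples.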

Other observations

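Islet amyloid polypeptide, Iapp, chosen after its values were seen, is stored with insulin in the β-cell granule and moved apart from it. In Db islets it was 5.10-fold higher (log2 fold change 2.35 ± 0.28 SE, edgeR adjusted p = 1.11e-07) while Ins2 was lower, so Ins2 counts per Iapp count were 63 and 82.8 in controls and 7.74 and 7.44 in Db libraries. In islets labelled TSC1 KO both fell, Iapp 4.24-fold (-2.08 ± 0.40, edgeR adjusted p = 0.0234), and the ratio was 23 and 22.4 in controls and 2.44 and 3.33 in the knockout libraries. Within the insulin pair, Ins2 counts per Ins1 count were 1.95 and 2.17 in RC controls and 0.639 and 0.934 in TSC1 KO. They were 3.11 and 3.01 in BKS controls and 2.6 and 2.19 in Db, with the caution that reads of close copies are uncertain. In every library of both models these ratios lay below those of its controls (2 against 2).

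Pappa2, a protease that frees insulin-like growth factors, fell in islets labelled TSC1 KO and rose in Db islets (-3.55 ± 0.80 and 4.17 ± 0.26, edgeR adjusted p = 0.0426 and 1.31e-12). Albumin (Alb), a liver transcript, rose in the first and fell in the second (2.76 ± 0.53 and -4.64 ± 0.71, edgeR adjusted p = 0.0235 and 1.4e-05). Agxt2, a mitochondrial aminotransferase, fell in both (-4.30 ± 0.82 and -5.01 ± 0.95, edgeR adjusted p = 0.0232 and 9.63e-05). Genes higher in the knockout and lower in Db islets numbered 214, fewer than the 269 from independent lists (odds ratio 0.729, Fisher's exact p = 4.75e-05). That p-value also takes genes as independent and does not measure the spread between libraries.

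Fold changes of the age comparison correlated weakly and negatively across genes with those of both islet models, at Spearman -0.145 over 12557 genes for TSC1 KO and -0.111 over 12645 genes for Db, where genes are not independent replicates. GC content had different trends in the comparisons. Across genes, fold changes correlated with GC content at Spearman -0.244 for age, -0.055 for TSC1 KO and 0.397 for Db. The opposite trends of age and Db could account for part of their negative correlation. The TSC1 KO trend has the same sign as that of age. Correlations of age with the islet models were not computed with the GC trend removed. The median log2 fold change ran from 0.22 in the genes of lowest GC (39.7%) to -0.36 in those of highest (59.6%) for age. For Db it rose from -0.87 in the lowest (40%) to 0.50 in the second highest group (57.1%) and was 0.13 in the highest (60.1%).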
